A study of Mus musculus with 24 samples.

How the data were processed

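Polyadenylated RNA of jejunal crypts was sequenced from 24 mice of 4 genotypes on 2 days, with 3 mice per genotype and day; per the series design, each library came from a separate mouse. Tamoxifen had been given at 56 mg/kg on 3 consecutive days, and the groups were taken 24 h (day 1) or 48 h (day 2) after induction, per the labels. Genotypes, days and replicate numbers came from the labels, and the 3 files were joined to them by the submitters' code numbers. The Apc-lost codes form 1 run between 2 Apc-intact runs. Within a day, neither a batch of that run nor a drift along the codes could be told from Apc loss. A drift also enters the day difference of Apc loss.

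The deposited table of estimated counts holds expected counts per gene, 1 line for each of 37620 Ensembl gene identifiers joined to a symbol. The submitters' processing notes name kallisto 0.43 and the genome build mm9 for them, and DESeq2 and DESeq for the normalised values. The annotation release and the way transcripts were summed to genes are not given in the sources used here. A second table by the authors holds normalised values, a signal on a linear scale: checked against the first, each column is the rounded estimated count divided by 1 size factor per library. The normalised values served only for this check, and the TPM table was not used.

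Estimated counts were rounded and tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by the edgeR filter with a minimum count of 10 over the 8 groups, which left 16552. Libraries were scaled by TMM, and a model with 1 mean per group was fitted to all 24 libraries by the robust quasi-likelihood method, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Values on the log2 scale used a prior count of 2. Library totals were 17.86 to 26.47 M estimated counts, tested genes held at least 99.92% of them, and the biological coefficient of variation was 17.6%. The median log2 change over all tested genes was moved by no scaling by more than 0.1.

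The comparisons on each day were Nle1 loss with Apc intact and lost, Apc loss with Nle1 present and lost, and their interaction. Days were compared for Control, Nle1 loss in both Apc states and Apc loss with Nle1 present. Effects were correlated across genes between comparisons. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and list members were adjusted over the list alone. The lists, with genes tested of those on the list, were p53 targets (38 of 40), Wnt targets (28 of 30), stem cell (25 of 25), Paneth cell (19 of 22), goblet cell (22 of 22), enteroendocrine cell (25 of 25), tuft cell (19 of 22), enterocyte (31 of 32), ribosome biogenesis (53 of 54), ribosomal proteins (79 of 79), S phase (32 of 32), G2 and M phase (34 of 34), immune cell (29 of 30), stromal and endothelial cell (16 of 24), interferon response (30 of 30), integrated stress response (28 of 30), fetal and regeneration (25 of 28) and the Notch pathway (20 of 21). Of the Wnt targets 7 are also on another list, as are 7 stem cell markers, 2 Notch pathway genes, and 1 each of the Paneth, goblet, enteroendocrine and stress response lists.

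Comparisons, tests, lists, alternatives and the rule for naming genes were written before the data were examined. By that rule Nle1 and Apc were named everywhere; a main comparison named the 5 most raised and 5 most lowered genes with an adjusted p under 0.05, a mean of at least 5 CPM, no overlap between the libraries of the 2 groups, and a symbol other than a provisional one. Interactions and differences between days named 3 and 3 without the condition on overlap, and each list up to 4 members with the smallest p. Alternatives were DESeq2 1.42.0 with its own test, DESeq2 size factors in edgeR, no filter beyond 1 count, a stricter filter of 2 CPM in 3 libraries, a term for replicate number, a fit to only the libraries compared, and leaving out each library in turn. A term for sex, read from Y-linked genes, and leaving out 3 libraries that stood apart were added after seeing the data. A fold against a group with 0 counts was taken against a floor of 3 counts per library.

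The procedure was tested on simulated data with 200 changed genes of 16163. For Nle1 loss with Apc intact on day 1, edgeR recovered 37.3%, 65.7% and 95.5% of the genes changed 1.5-fold, 2-fold and 4-fold, with 6 false calls of 138 (4.35%). For the interaction on day 2 it recovered 11.9%, 44.8% and 86.4%, with 6 false calls of 101 (5.94%). DESeq2 recovered 44.8%, 70.1% and 97% in the first and 17.9%, 52.2% and 90.9% in the second, with 27 and 22 false calls. Words of 31 bases shared between genes were counted on a mouse transcript reference (GENCODE M21), and the order of genes near Apc was taken from its annotation (GRCm38); neither served for quantification.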

Results

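Polyadenylated RNA was sequenced from jejunal crypts of 24 mice, and each library came from 1 mouse. The mice belonged to 4 genotypes: Control, a conditional knockout of the Notchless gene Nle1 (NlecKO), a conditional knockout of Apc (ApccKO), and a knockout of both genes (ApccKO combined with NlecKO, called the double knockout here). Crypts were taken on day 1 or day 2 after induction with tamoxifen, that is after 24 or 48 h, with 3 mice in each of the 8 groups. The Notchless protein takes part in the assembly of the large ribosomal subunit, and the APC protein restrains Wnt signalling. The libraries held 17.86 to 26.47 M estimated counts, with a median of 19.82 M, and 16552 of 37620 genes passed the filter on low counts. The 10 most abundant genes took 6.47% to 10.4% of the counts of a library. Values of a gene in a group are given as the mean ± SD in CPM (counts scaled to the same library size) over 3 mice, and fold changes as log2 ± SE. Adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested unless another test is named.

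Within groups, pairs of libraries correlated at 0.9752 to 0.9884 across genes, which are not independent replicates. The first principal component held 54.3% of the variance and separated libraries by Apc state, and the second held 12.4% and separated them by Nle1 state. Y-linked genes marked 9 libraries as male and 15 as female, with 2 males in the NlecKO group of day 2 and 1 in every other group. In 3 libraries of Apc-lost crypts on day 1, ApccKO replicates 2 and 3 and double knockout replicate 3, the transcripts Gm8730 and Gm9625 lay under 1 CPM, against at least 33 CPM in the other 21 libraries. The same 3 libraries had lactase (Lct) at 321 to 476 CPM, where the other Apc-lost libraries had 10.5 to 128 CPM. These 3 transcripts and the 3 libraries were singled out after their values were seen. Leaving these libraries out keeps 1 ApccKO library on day 1, so gene counts and p values of that fit are not given.

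**Figure D1:**
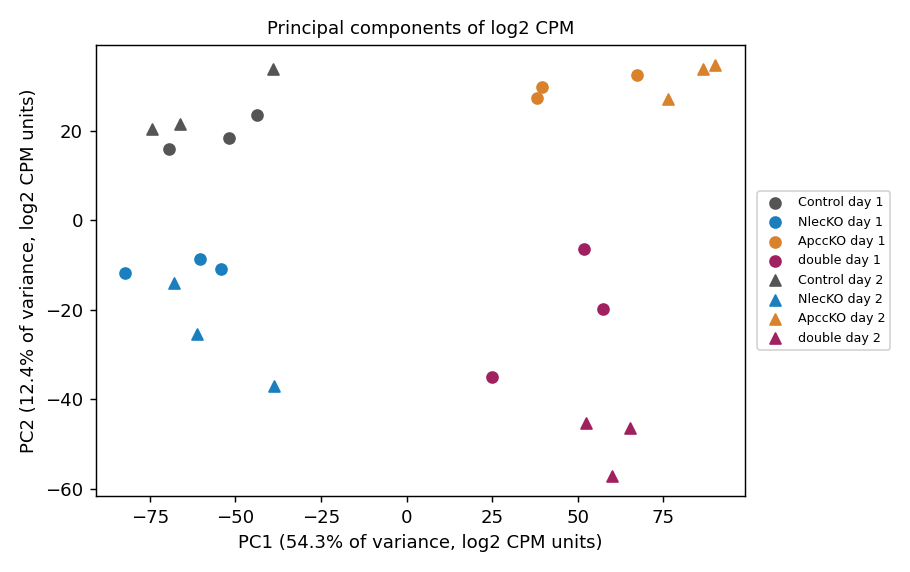
Principal components of log2 CPM of the 16552 tested genes, with 1 point per library and the share of variance on each axis. Libraries separate along the first component by Apc state (54.3% of the variance) and along the second by Nle1 state (12.4%).

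The targeted transcripts were read first. Nle1 (ENSMUSG00000020692) fell in every comparison of Nle1 loss. Control crypts held 24.8±2.6 CPM on day 1 and 22.7±4.5 CPM on day 2, and NlecKO crypts 5.53±0.84 and 6.69±1.0 CPM, or 22.3% and 29.4% of Control. The log2 fold changes were -2.16±0.17 on day 1 (adjusted p = 8.7e-07) and -1.77±0.17 on day 2 (adjusted p = 2.5e-06). Without Apc, Nle1 went from 37.2±2.3 to 9.59±2.4 CPM on day 1 (-1.95±0.17, adjusted p = 5.2e-07). On day 2 it went from 34.9±1.1 to 9.8±1.1 CPM (-1.83±0.17, adjusted p = 1.8e-07). This left 25.8% and 28.1% of the level in ApccKO crypts. Apc loss by itself raised Nle1 by 0.58±0.16 on day 1 (adjusted p = 0.0048) and by 0.62±0.16 on day 2 (adjusted p = 0.0024). Apc (ENSMUSG00000005871) was counted at 130 to 147 CPM in all 8 groups and was not called for Apc loss on day 1 (adjusted p = 0.22) or day 2 (adjusted p = 0.97). Counts over the whole gene do not show a deletion of part of it, so the Apc labels were not checked by the Apc transcript itself.

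**Figure D2:**
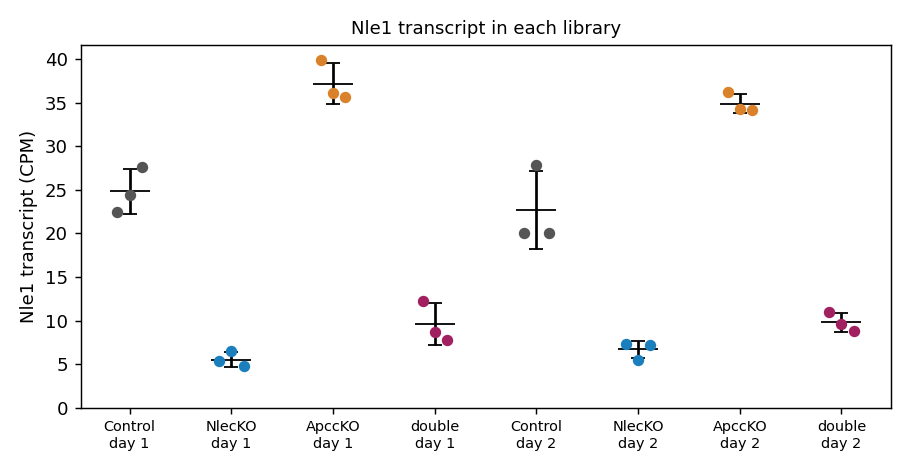
Nle1 transcript in CPM per library, with 3 mice in each of the 8 groups and the mean ± SD drawn. The NlecKO and double knockout libraries lie below the Control and ApccKO libraries on both days, with group means of 5.53 to 9.8 CPM against 22.7 to 37.2 CPM.

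The comparison of NlecKO with Control crypts on day 1 asked what the loss of Notchless does early in crypts with intact Apc. Targets of the tumour suppressor p53 rose, among them the cell cycle inhibitor Cdkn1a, and 19 of 32 genes of DNA replication and 5 of 34 of division fell. Markers of enteroendocrine cells rose in part, while no Wnt target and no ribosome assembly gene passed. Summed enterocyte markers stood at 33300±10900 CPM in Control and 53700±5480 CPM in NlecKO crypts, and stromal markers at 52.6±1.56 and 85.8±13.2 CPM. In all, 144 genes were higher and 267 lower among 411 called, and 63 of these changed at least 2-fold. Cdkn1a (ENSMUSG00000023067) went from 150±16 to 369±54 CPM (1.30±0.21, adjusted p = 0.0058). The RNA-binding protein gene Zmat3 (ENSMUSG00000027663, 1.51±0.20, adjusted p = 0.0012) rose too. So did cyclin G1, Ccng1 (ENSMUSG00000020326, 1.16±0.18, adjusted p = 0.0043), and the reductase gene Dcxr (ENSMUSG00000039450, 0.91±0.14, adjusted p = 0.0043). Among the genes raised most was the LIM domain gene Crip2 (ENSMUSG00000006356, 3.56±0.92 to 21±9.2 CPM, 2.56±0.48, adjusted p = 0.014). Phlda3 (ENSMUSG00000041801), whose product restrains Akt (13.3±5.1 to 68±28 CPM, 2.35±0.38, adjusted p = 0.007), and the kinase gene Plk2 (ENSMUSG00000021701, 13.2±4.1 to 49.3±13 CPM, 1.90±0.34, adjusted p = 0.011), rose strongly as well. Behind Nle1, the genes lowered most included the gasdermins Gsdmc2 (ENSMUSG00000056293, -2.14±0.51, adjusted p = 0.036) and Gsdmc4 (ENSMUSG00000055748, -2.09±0.51, adjusted p = 0.04). They also included the atypical E2F factor E2f8 (ENSMUSG00000046179, 66.6±8.1 to 31.6±2.8 CPM, -1.07±0.16, adjusted p = 0.0043) and Bard1 (ENSMUSG00000026196), the partner of the BRCA1 protein (-1.01±0.15, adjusted p = 0.0033). The gasdermin C genes share 51.2% to 63.9% of their 31-base words with one another, so their separate values are uncertain.

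Gene lists fixed beforehand gave the same picture on day 1 with Apc intact. Of 38 tested p53 targets, 21 were higher, 17 did not pass, and 0 were lower by edgeR (0 lower at an unadjusted p under 0.05 and by DESeq2). Adjusted over the list alone, 32 were higher. The list stood out by camera (adjusted p = 4.2e-29) and held with adjusted p = 0.042 with an estimated correlation. In the S phase list, 19 of 32 genes were lower (30 adjusted over the list alone, camera adjusted p = 2.7e-26). This call was lost at adjusted p = 0.11 with an estimated correlation. Cyclin E1, Ccne1 (ENSMUSG00000002068, -0.86±0.15, adjusted p = 0.007), and the DNA methylation factor Uhrf1 (ENSMUSG00000001228, -0.90±0.16, adjusted p = 0.011) were among the lower genes. Of 34 G2 and M phase genes, 5 were lower (31 adjusted over the list alone, camera adjusted p = 5.6e-21). It then fell away, at adjusted p = 0.21 with an estimated correlation. The proliferation marker Mki67 (ENSMUSG00000031004) fell from 375±59 to 213±31 CPM (-0.81±0.16, adjusted p = 0.015). Enteroendocrine markers had 3 of 25 higher (10 adjusted over the list alone, camera adjusted p = 1.7e-09). That call ended at adjusted p = 0.11 with an estimated correlation. The serotonin enzyme gene Tph1 (ENSMUSG00000040046) was among them (1.0±0.19, adjusted p = 0.011).

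Few members of the other lists passed on day 1 with Apc intact. The stem cell list had 1 of 25 higher, Tnfrsf21 (ENSMUSG00000023915, 0.60±0.11, adjusted p = 0.011), and 1 higher and 1 lower adjusted over the list alone. Smoc2, another marker on it, did not pass (-0.69±0.19, adjusted p = 0.058). Stromal and endothelial markers had 1 of 16 higher (4 adjusted over the list alone), and the fetal and regeneration list 1 of 25 (1 adjusted over the list alone). The remaining lists had 0 called by edgeR: Wnt targets (2 higher and 1 lower at an unadjusted p under 0.05, 1 higher by DESeq2), ribosome biogenesis genes (0 and 3, 0 by DESeq2) and immune cell markers (4 and 0, 0 by DESeq2) among them. Atf4 (0.26±0.09, adjusted p = 0.11) and Notch3 (1.60±0.43, adjusted p = 0.058) did not pass. For Wnt targets and immune markers the median change was negative (-0.01 and -0.09) and the mean positive (0.03 and 0.27).

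The day 1 count with Apc intact rested on single libraries. It was 1159 without Control replicate 1, 49 and 29 without Control replicates 2 and 3, and 127, 124 and 52 without NlecKO replicates 1, 2 and 3. It was 6 when only the 6 libraries compared were fitted, where the genes named here other than Nle1, E2f8, Cdkn1a and Gsdmc4 had adjusted p values of 0.051 to 0.1. Nle1, Cdkn1a and E2f8 passed in every alternative. Gsdmc2 and Gsdmc4 lost their calls without any 1 library except Control replicate 1 (adjusted p = 0.087 to 0.22). Crip2 lost it without Control replicate 2 or 3 or NlecKO replicate 3 (adjusted p = 0.059 to 0.075), and Plk2 without Control replicate 3 or NlecKO replicate 3 (adjusted p = 0.068 and 0.054). Ccne1 and Uhrf1 lost it without Control replicate 3 (adjusted p = 0.052 and 0.075), and Mki67 without Control replicates 2 or 3 or NlecKO replicates 1 or 3 (adjusted p = 0.059 to 0.11). Tph1 and Tnfrsf21 lost it without Control replicate 2 or 3 (adjusted p = 0.067 to 0.097), and Tnfrsf21 also without NlecKO replicate 3 (adjusted p = 0.059).

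On day 2 the same comparison asked how the response to Notchless loss stood a day later. Targets of p53 were higher and division genes lower, and some ribosome assembly, fetal and regeneration, and stress response genes were higher. Some enteroendocrine markers were higher, and the stem cell markers Smoc2 and Olfm4 fell. Summed enterocyte markers stood at 33700±15900 CPM in Control and 48500±7340 CPM in NlecKO crypts. There were 1214 genes higher and 1367 lower among 2581 called, of which 549 changed at least 2-fold. Raised most were Zfp365 (ENSMUSG00000037855), a p53 target tied to replication stress (0.265±0.28 to 12.6±8.7 CPM, 5.59±0.74, adjusted p = 9.3e-05), and the membrane transporter gene Slc4a11 (ENSMUSG00000074796, 5.44±0.71, adjusted p = 8.2e-05). Next came the autophagy gene Atg9b (ENSMUSG00000038295, 5.18±0.80, adjusted p = 0.00042), then Crip2 (1.48±0.63 to 45±31 CPM, 4.90±0.53, adjusted p = 1.8e-05) and the drug efflux pump gene Abcb1b (ENSMUSG00000028970, 2.6±0.93 to 47.5±22 CPM, 4.20±0.39, adjusted p = 4.1e-06). Lowered most were Gsdmc3 (ENSMUSG00000055827, 16.2±10 to 0.728±0.6 CPM, -4.43±0.57, adjusted p = 4.5e-05), Gsdmc2 (-3.81±0.52, adjusted p = 0.00011) and Gsdmc4 (-3.44±0.52, adjusted p = 0.00032), which share reads. They were followed by the RNA-binding gene Ybx2 (ENSMUSG00000018554, -2.19±0.32, adjusted p = 0.00016) and the transcription factor gene Mycn (ENSMUSG00000037169, 11.1±2.9 to 2.86±0.47 CPM, -1.97±0.26, adjusted p = 4.8e-05).

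On day 2 with Apc intact, 31 of 38 p53 targets were higher and 0 lower by edgeR (1 lower at an unadjusted p under 0.05 and 0 by DESeq2), with 32 higher adjusted over the list alone. Camera gave an adjusted p = 1.5e-29, which held at adjusted p = 0.039 with an estimated correlation. Zmat3 rose from 26.1±3.0 to 154±50 CPM (2.56±0.20, adjusted p = 5.9e-07). Ccng1 (2.18±0.19, adjusted p = 9.1e-07) and the death receptor gene Eda2r (ENSMUSG00000034457, 3.14±1.2 to 46±15 CPM, 3.85±0.32, adjusted p = 1e-06) followed. Eda2r had itself fallen in Control crypts between the days, from 11.3±3.8 CPM, and Gsdmc3 had risen from 2.27±0.67 CPM. Among ribosome biogenesis genes 34 of 53 rose (39 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.2e-16). That camera call was lost at adjusted p = 0.36 with an estimated correlation. The assembly and export factor genes Ltv1 (ENSMUSG00000019814, 0.53±0.09, adjusted p = 0.0008), Nmd3 (ENSMUSG00000027787, 0.71±0.13, adjusted p = 0.001) and Brix1 (ENSMUSG00000022247, 0.74±0.14, adjusted p = 0.0015) rose. The G2 and M phase list had 31 of 34 lower (32 adjusted over the list alone, camera adjusted p = 8.9e-18). Its call was lost at adjusted p = 0.28 with an estimated correlation. It was led by Nusap1 (ENSMUSG00000027306) of the spindle (-1.04±0.15, adjusted p = 0.0001), Mki67 (-1.0±0.16, adjusted p = 0.00044) and cyclin B2, Ccnb2 (ENSMUSG00000032218, -1.12±0.19, adjusted p = 0.0006). S phase genes had 14 of 32 lower (19 adjusted over the list alone, camera adjusted p = 2.3e-08). The S phase call was lost at adjusted p = 0.43 with an estimated correlation. Uhrf1 was among the lower ones (-0.79±0.16, adjusted p = 0.0029).

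Fetal and regeneration genes had 13 of 25 higher on day 2 with Apc intact (20 adjusted over the list alone, camera adjusted p = 8.4e-12). The list no longer passed, at adjusted p = 0.085 with an estimated correlation. The EGF receptor ligand genes Areg (ENSMUSG00000029378, 3.11±0.71 to 49.2±32 CPM, 4.0±0.45, adjusted p = 2.3e-05) and Ereg (ENSMUSG00000029377, 3.18±0.39, adjusted p = 4e-05) rose most clearly. The integrated stress response had 7 of 28 higher, also 7 adjusted over the list alone (camera adjusted p = 0.00051). It was lost at adjusted p = 0.28 with an estimated correlation. The stress factor genes Atf4 (ENSMUSG00000042406, 154±5.4 to 220±27 CPM, 0.51±0.09, adjusted p = 0.00055) and Ddit3 (ENSMUSG00000025408, 0.77±0.15, adjusted p = 0.0017) rose. Enteroendocrine markers had 12 of 25 higher (14 adjusted over the list alone, camera adjusted p = 9.2e-06). This call, too, was lost at adjusted p = 0.28 with an estimated correlation. Reg4 (ENSMUSG00000027876, 1.47±0.20, adjusted p = 8.6e-05) and the granin gene Chgb (ENSMUSG00000027350, 0.79±0.14, adjusted p = 0.00082) rose. The stem cell list had 3 higher and 4 lower of 25 (4 and 6 adjusted over the list alone, camera adjusted p = 0.5). Tnfrsf21 rose (0.87±0.11, adjusted p = 4e-05). The crypt base markers Smoc2 (ENSMUSG00000023886, 97.9±11 to 54.7±12 CPM, -0.84±0.19, adjusted p = 0.0053) and Olfm4 (ENSMUSG00000022026, 1360±210 to 679±270 CPM, -1.0±0.24, adjusted p = 0.0086) fell.

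Wnt targets had 5 higher and 1 lower of 28 on day 2 with Apc intact (7 and 1 adjusted over the list alone, camera adjusted p = 0.16), with the surface glycoprotein gene Cd44 (ENSMUSG00000005087) at 1.48±0.23 (adjusted p = 0.0004). The Notch pathway had 3 higher and 1 lower of 20 (3 and 2 adjusted over the list alone, camera adjusted p = 0.8). Higher were Notch3 (ENSMUSG00000038146, 3.00±0.45, adjusted p = 0.00031) and the ligand genes Jag2 (ENSMUSG00000002799, 1.84±0.31, adjusted p = 0.00077) and Jag1 (ENSMUSG00000027276, 1.08±0.20, adjusted p = 0.0011). Paneth, goblet, tuft and immune cell markers had 0 genes called by edgeR and no camera call (adjusted p = 0.46, 0.98, 0.17 and 0.52). At an unadjusted p under 0.05 the counts, higher and lower, were 1 and 1, 2 and 0, 0 and 0, and 0 and 1. DESeq2 called 0 except 2 higher goblet markers. Medians, means and the camera direction differed in sign for the Paneth (0.18, -0.03, higher), goblet (-0.10, 0.09, lower) and Notch lists (-0.06, 0.26, higher). The count of 2581 was 1673 without Control replicate 2, 1206 without NlecKO replicate 3, and 279 when only the 6 libraries compared were fitted. In that fit the gasdermins, Atg9b, Ybx2, Cd44, Olfm4, Ltv1, Nmd3, Brix1, Uhrf1, Ccnb2, Atf4, Ddit3, Notch3 and Jag2 had adjusted p values of 0.052 to 0.083. Olfm4 also lost its call without NlecKO replicate 3 (adjusted p = 0.064).

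The comparison of ApccKO with Control crypts on day 1 asked what Apc loss does by itself. Wnt targets and stem cell markers rose, as did genes of ribosome assembly and DNA replication. Markers of enterocytes, tuft cells, enteroendocrine cells and of immune cells fell. About as many genes were higher (4088) as lower (4138) among 8226 called, and 2820 changed at least 2-fold. Raised most were the ribosomal protein genes Rps3a (ENSMUSG00000028081, 6.15±0.58 to 510±18 CPM, 6.37±0.19, adjusted p = 4.4e-15) and Rplp0 (ENSMUSG00000067274, 75.6±10 to 1960±570 CPM, 4.70±0.24, adjusted p = 1.5e-10). They were followed by Atg9b (0.66±0.26 to 35.8±16 CPM, 5.74±0.86, adjusted p = 5.6e-05), the death inhibitor gene Faim2 (ENSMUSG00000023011, 5.40±0.68, adjusted p = 8.2e-06) and the phospholipase gene Pla2g5 (ENSMUSG00000041193, 8.02±2.6 to 160±12 CPM, 4.31±0.38, adjusted p = 2e-07). Rps3a and Rplp0 share 76.9% and 42.8% of their 31-base words with near-identical copies, so their values are uncertain. Lowered most were amphiphysin, Amph (ENSMUSG00000021314, 12.7±3.1 to 0.0633±0.074 CPM, -7.49±0.64, adjusted p = 6.2e-08), and carbonic anhydrase 4, Car4 (ENSMUSG00000000805, 93.6±42 to 1.51±0.57 CPM, -5.95±0.39, adjusted p = 5.6e-09). Below them came Gsdmc4 (-5.36±0.66, adjusted p = 6.9e-06) and the glucuronosyltransferases Ugt2b5 (ENSMUSG00000054630, -5.35±0.75, adjusted p = 2.9e-05) and Ugt1a9 (ENSMUSG00000090175, -4.75±0.76, adjusted p = 8.6e-05), which share 56.4% and 67.8% of their words with other genes.

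Wnt targets were higher in 22 and lower in 1 of 28 on day 1 of Apc loss, by either adjustment, over all genes or over the list alone (camera adjusted p = 4.2e-13). Its call did not hold, at adjusted p = 0.059 with an estimated correlation. The feedback genes Rnf43 (ENSMUSG00000034177, 79.5±0.37 to 269±9.9 CPM, 1.76±0.09, adjusted p = 5.2e-11) and Axin2 (ENSMUSG00000000142, 111±13 to 462±33 CPM, 2.05±0.15, adjusted p = 7.9e-09) rose. So did the transcription factor gene Tcf7 (ENSMUSG00000000782, 1.93±0.13, adjusted p = 1.6e-09) and the receptor gene Tnfrsf19 (ENSMUSG00000060548, 5.57±1.2 to 110±14 CPM, 4.30±0.27, adjusted p = 2.2e-09). Of 25 stem cell markers 24 were higher, by either adjustment (camera adjusted p = 3.4e-16). This was lost at adjusted p = 0.059 with an estimated correlation. Ribosome biogenesis genes were higher in 51 of 53 (51 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.6e-14), with Rrp1b (ENSMUSG00000058392) at 1.26±0.16 (adjusted p = 6.3e-06) and Gnl3 (ENSMUSG00000042354) at 0.79±0.11 (adjusted p = 1.7e-05). S phase genes were higher in 31 of 32, by either adjustment (camera adjusted p = 1.4e-11). These 2 calls were lost at adjusted p = 0.38 with an estimated correlation. The replication licensing gene Mcm2 (ENSMUSG00000002870) rose by 1.14±0.15 (adjusted p = 9.7e-06). Ribosomal proteins were higher in 34 of 79 (28 adjusted over the list alone, camera adjusted p = 1.4e-07) and G2 and M phase genes in 21 of 34 (24 adjusted over the list alone, camera adjusted p = 2.8e-05). They were lost at adjusted p = 0.5 and 0.53 with an estimated correlation.

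Markers of mature cells moved the other way on day 1 of Apc loss. Enterocyte genes were lower in 23 of 31 (26 adjusted over the list alone, camera adjusted p = 6e-07). The call was lost at adjusted p = 0.42 with an estimated correlation. The chloride exchanger gene Slc26a3 (ENSMUSG00000001225, -2.73±0.37, adjusted p = 2.1e-05) and the lipoprotein assembly gene Mttp (ENSMUSG00000028158, -2.25±0.43, adjusted p = 0.00039) fell. Tuft cell markers were lower in 13 of 19, by either adjustment (camera adjusted p = 2.8e-05), and immune markers in 20 of 29, by either adjustment (camera adjusted p = 7.7e-06). Each of these was lost at adjusted p = 0.38 with an estimated correlation. Enteroendocrine markers were lower in 16 and higher in 2 of 25 (17 and 2 adjusted over the list alone, camera adjusted p = 0.00014), and goblet markers lower in 11 and higher in 1 of 22 (12 and 1 adjusted over the list alone, camera adjusted p = 0.0038). They, too, were lost at adjusted p = 0.38 with an estimated correlation. The T cell receptor gene Cd3e (ENSMUSG00000032093, 28.6±8.0 to 6.02±0.97 CPM, -2.25±0.25, adjusted p = 1.2e-06) and the granzyme gene Gzmb (ENSMUSG00000015437, -2.36±0.33, adjusted p = 2.4e-05) fell. The incretin gene Gip (ENSMUSG00000014351, -1.56±0.15, adjusted p = 2.9e-07) and the mucus gene Tff3 (ENSMUSG00000024029, -1.01±0.12, adjusted p = 1.6e-06) fell as well.

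The Paneth list had 5 of 19 higher on day 1 of Apc loss (1 adjusted over the list alone, camera adjusted p = 0.35), with a median of -0.01 and a mean of 0.65. Interferon response genes were lower in 10 and higher in 2 of 30 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0086). It then fell away, at adjusted p = 0.59 with an estimated correlation. Fetal genes were higher in 14 and lower in 3 of 25, by either adjustment (camera adjusted p = 0.0017), with clusterin, Clu (ENSMUSG00000022037), at 3.66±0.49 (adjusted p = 1.9e-05). That call was lost at adjusted p = 0.38 with an estimated correlation. The p53 targets were split, 12 higher and 6 lower of 38 (12 and 5 adjusted over the list alone, camera adjusted p = 0.22). So was the integrated stress response, 10 higher and 4 lower of 28 (10 and 5 adjusted over the list alone, camera adjusted p = 0.15). Leaving out the 3 libraries that stood apart keeps 1 ApccKO library on day 1, which has no spread of its own. Whether these results depend on those libraries could not be tested.

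The effect of Apc loss was also read on day 2. Wnt targets were higher, clusterin and other fetal genes rose, and mature cell markers were lower. In all 9708 genes were called, 4839 higher and 4869 lower, of which 3993 changed at least 2-fold. Raised most were the imprinted RNA H19 (ENSMUSG00000000031, 0.176±0.13 to 29.5±9.3 CPM, 7.35±0.99, adjusted p = 6.9e-06), and osteoprotegerin, Tnfrsf11b (ENSMUSG00000063727, 0.092±0.12 to 12.9±2.0 CPM, 6.81±0.49, adjusted p = 1.4e-09). Next were a collagen gene, Col16a1 (ENSMUSG00000040690, 6.66±0.83, adjusted p = 3.3e-06), the homeobox gene Msx1 (ENSMUSG00000048450, 6.66±0.64, adjusted p = 1.2e-07) and Clu (3.08±0.74 to 264±59 CPM, 6.39±0.53, adjusted p = 3.3e-08). Lowered most was Sco2 (ENSMUSG00000091780), which helps assemble cytochrome c oxidase and had 0 counts in ApccKO on day 2 (16.1±8.7 CPM in Control, at least 119-fold lower at 3 counts per library, adjusted p = 1.5e-06). Next were Car4 (195±49 to 0.163±0.1 CPM, -10.16±0.51, adjusted p = 8.4e-11), Ugt2b5 (-10.07±1.2, adjusted p = 1.5e-06), Gsdmc4 (-8.99±0.77, adjusted p = 4.4e-08) and the sugar transporter gene Slc5a4a (ENSMUSG00000020229, -8.43±1.2, adjusted p = 1.7e-05). Sco2 shares 66.2% of its words with another gene, so its value is uncertain.

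By list, Wnt targets were higher in 23 and lower in 1 of 28 on day 2 of Apc loss, by either adjustment (camera adjusted p = 4.1e-12). The list no longer passed, at adjusted p = 0.08 with an estimated correlation. Rnf43 (1.92±0.09, adjusted p = 6.4e-12) and the guidance receptor gene Ephb3 (ENSMUSG00000005958, 2.70±0.18, adjusted p = 6.5e-10) rose. Stem cell markers were higher in 20 of 25 (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 6.6e-10). Tuft cell markers were lower in 18 of 19, by either adjustment (camera adjusted p = 5.8e-09). Each of these was lost at adjusted p = 0.25 with an estimated correlation. Fetal genes were higher in 19 and lower in 2 of 25, by either adjustment (camera adjusted p = 1.7e-06). They were lost at adjusted p = 0.25 with an estimated correlation. Enterocyte genes were lower in 29 of 31 (29 lower and 1 higher adjusted over the list alone, camera adjusted p = 8.7e-09), and immune markers in 24 of 29, by either adjustment (camera adjusted p = 6.6e-09). Both were lost at adjusted p = 0.29 with an estimated correlation. Goblet markers were lower in 12 and higher in 2 of 22, by either adjustment (camera adjusted p = 0.0013), and enteroendocrine markers lower in 18 and higher in 2 of 25 (18 and 3 adjusted over the list alone, camera adjusted p = 7.5e-05). Both of these ended at adjusted p = 0.29 with an estimated correlation. Ribosome biogenesis genes were higher in 51 of 53 (51 higher and 1 lower adjusted over the list alone, camera adjusted p = 2e-12), and S phase genes higher in 30 and lower in 1 of 32, by either adjustment (camera adjusted p = 8.7e-09). They stood at adjusted p = 0.29 with an estimated correlation.

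The mucus genes Tff3 (808±47 to 162±22 CPM, -2.31±0.12, adjusted p = 2.6e-11) and Fcgbp (ENSMUSG00000047730, 7940±910 to 1180±320 CPM, -2.75±0.18, adjusted p = 6.9e-10) fell on day 2 of Apc loss. Gip fell (-2.87±0.16, adjusted p = 8.4e-11), as did the tuft cell genes Alox5 (ENSMUSG00000025701, 9.13±2.7 to 0.209±0.066 CPM, -5.40±0.42, adjusted p = 4.1e-09) and Dclk1 (ENSMUSG00000027797, -4.46±0.38, adjusted p = 2.8e-08). Slc26a3 (-4.49±0.41, adjusted p = 9.4e-08), Cd3e (-2.97±0.26, adjusted p = 2.1e-08) and the granzyme gene Gzma (ENSMUSG00000023132, -3.20±0.31, adjusted p = 1.2e-07) were lower. The phospholipase gene Pla2g2a (ENSMUSG00000058908, 3.04±0.31, adjusted p = 2.9e-07) and matrilysin, Mmp7 (ENSMUSG00000018623, 104±38 to 744±190 CPM, 2.84±0.33, adjusted p = 1.3e-06), were among 5 of 19 Paneth markers that rose (4 adjusted over the list alone, camera adjusted p = 0.12). The amino acid transporter gene Slc7a5 (ENSMUSG00000040010, 2.23±0.22, adjusted p = 1.7e-07) and the fetal marker Anxa1 (ENSMUSG00000024659, 0.94±0.18 to 20.4±7.4 CPM, 4.43±0.45, adjusted p = 2.1e-07) rose. The p53 targets were again split, 12 higher and 5 lower of 38, by either adjustment (camera adjusted p = 0.18). Effects of Apc loss on the 2 days correlated at 0.816 (Pearson) and 0.844 (Spearman) across genes, which are not independent replicates. Of 7151 genes called on both days, 7139 had the same sign.

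**Figure D3:**
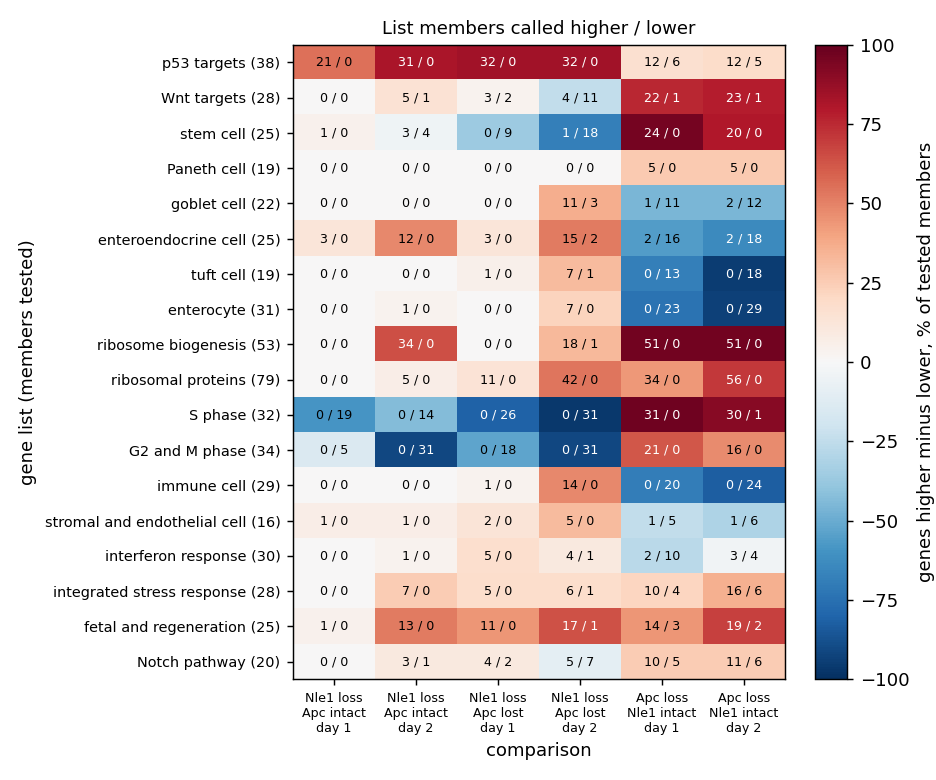
Number of members of each gene list called higher and lower in the 6 main comparisons, by edgeR with adjusted p under 0.05 over all genes. The p53 list is higher in 21 to 32 of 38 genes in each comparison of Nle1 loss, and the S phase list is lower in 14 to 31 of 32.

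Double knockout crypts were set against ApccKO crypts on day 1 to ask what Notchless loss does once Apc is lost. The p53 targets rose again, and 26 of 32 replication and 18 of 34 division genes fell. Some stem cell markers, such as Olfm4, fell, and the Notch receptor gene Notch3, some fetal genes and the stress factor gene Atf4 rose. There were 972 genes higher and 790 lower among 1762 called, 400 of them changed at least 2-fold. Raised most were the adhesion molecule gene Mcam (ENSMUSG00000032135, 17.3±11 to 173±11 CPM, 3.32±0.40, adjusted p = 8e-05), and the G protein gene Gna15 (ENSMUSG00000034792, 3.30±0.49, adjusted p = 0.00039). Behind them were the vitamin C synthesis gene Gulo (ENSMUSG00000034450, 3.12±0.52, adjusted p = 0.00094), Crip2 (8.21±3.3 to 70.1±6.1 CPM, 3.09±0.45, adjusted p = 0.00039) and the carnitine transferase gene Cpt1c (ENSMUSG00000007783, 3.08±0.39, adjusted p = 9.8e-05). Lowered most, besides Nle1, were the Wnt antagonist gene Sfrp5 (ENSMUSG00000018822, 31.1±12 to 6.61±3.8 CPM, -2.23±0.48, adjusted p = 0.007), and the Schlafen gene Slfn9 (ENSMUSG00000069793, 92.6±3.7 to 29±4.4 CPM, -1.67±0.14, adjusted p = 4.2e-07). Smaller falls were those of the growth factor carrier gene Fgfbp1 (ENSMUSG00000048373, -1.46±0.24, adjusted p = 0.00063) and the matrix gene Prelp (ENSMUSG00000041577, -1.42±0.35, adjusted p = 0.014).

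Of the p53 targets, 32 of 38 were higher and 0 lower by edgeR without Apc on day 1 (0 lower at an unadjusted p under 0.05 and by DESeq2), and 33 were higher adjusted over the list alone. Camera gave adjusted p = 2.2e-35, and the call held at adjusted p = 0.019 with an estimated correlation. Dcxr (20.7±0.078 to 78.4±8.0 CPM, 1.92±0.14, adjusted p = 1.7e-07) and the p53-induced gene Ei24 (ENSMUSG00000062762, 0.75±0.08, adjusted p = 4e-06) rose. Cdkn1a (103±7.6 to 448±68 CPM, 2.12±0.21, adjusted p = 5.2e-06) and Ccng1 (1.71±0.18, adjusted p = 1e-05) rose too. S phase genes were lower in 26 of 32 (30 adjusted over the list alone, camera adjusted p = 2.6e-21), with E2f1 (ENSMUSG00000027490) at -1.06±0.20 (adjusted p = 0.0021). Its call did not hold, at adjusted p = 0.17 with an estimated correlation. G2 and M phase genes were lower in 18 of 34 (26 adjusted over the list alone, camera adjusted p = 7.6e-16), with Mki67 at -0.77±0.16 (adjusted p = 0.0053). Stem cell markers were lower in 9 of 25 (11 adjusted over the list alone, camera adjusted p = 7.3e-07). Both lists were lost at adjusted p = 0.35 with an estimated correlation. Olfm4 (4710±150 to 2210±620 CPM, -1.09±0.24, adjusted p = 0.0077) and the water channel gene Aqp4 (ENSMUSG00000024411, -1.12±0.23, adjusted p = 0.0042) fell. Wnt targets had 3 higher and 2 lower of 28 (4 and 3 adjusted over the list alone, camera adjusted p = 0.48), the receptor gene Lgr5 (ENSMUSG00000020140) among the lower (-0.93±0.25, adjusted p = 0.023). Fetal genes were higher in 11 of 25 (18 adjusted over the list alone, camera adjusted p = 1.4e-09). Their call was lost at adjusted p = 0.17 with an estimated correlation. Keratin 19, Krt19 (ENSMUSG00000020911), rose from 911±83 to 1560±140 CPM (0.78±0.14, adjusted p = 0.0011). In the Notch pathway 4 were higher and 2 lower of 20, by either adjustment (camera adjusted p = 0.9). Notch3 rose (7.75±3.8 to 37.8±6.1 CPM, 2.28±0.41, adjusted p = 0.0018), as did Jag2 (1.53±0.30, adjusted p = 0.0035), and the glycosyltransferase gene Lfng (ENSMUSG00000029570) fell (-0.87±0.17, adjusted p = 0.0024). Atf4 rose by 0.55±0.09 (adjusted p = 0.00046).

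Ribosomal proteins were higher in 11 of 79 without Apc on day 1 (40 adjusted over the list alone, camera adjusted p = 2.9e-12), and interferon genes in 5 of 30 (27 adjusted over the list alone, camera adjusted p = 7.3e-08). Each call was lost at adjusted p = 0.44 with an estimated correlation. Ribosome biogenesis, Paneth, goblet and enterocyte lists had 0 called by edgeR (camera adjusted p = 0.48, 0.51, 0.42 and 0.27). At an unadjusted p under 0.05 their counts, higher and lower, were 4 and 1, 1 and 0, 5 and 0, and 2 and 0. DESeq2 called 1 lower ribosome biogenesis gene and 0 of the others. The median, mean and test differed in sign for Wnt targets (-0.01, 0.27, lower) and the Notch pathway (-0.04, 0.13, lower).

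Leaving out the 3 libraries that stood apart keeps 1 ApccKO library on day 1 (replicate 1). A fit with 1 library in a group cannot tell lost replication from dependence on the libraries left out. Its counts and p values are therefore not given. With all libraries camera called the stromal list (adjusted p = 0.021), a call lost at adjusted p = 0.44 with an estimated correlation. The count of 1762 was 1007, 1110 and 927 without ApccKO replicates 1, 2 and 3, 600 without double knockout replicate 3, and 535 when only the 6 libraries compared were fitted. Without double knockout replicate 3 the calls of Sfrp5 (adjusted p = 0.051), Prelp (adjusted p = 0.093), Olfm4 (adjusted p = 0.059) and Lgr5 (adjusted p = 0.14) ended. The call of Lgr5 also ended without ApccKO replicates 1 or 3 or double knockout replicate 1 (adjusted p = 0.059 to 0.086). In the fit to only the libraries compared, Gulo, Sfrp5, Aqp4, Mki67 and Lgr5 did not pass (adjusted p = 0.054 to 0.18).

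The same comparison on day 2 asked whether Notchless loss acts on Apc-lost crypts a day later. The p53 targets were again higher, and stem cell markers, Lgr5 and Olfm4 at their head, fell. Some goblet, enteroendocrine and tuft cell markers were higher than in ApccKO crypts, and replication and division genes were lower. With 3221 genes higher and 2554 lower, 5775 were called, and 1732 changed at least 2-fold. Raised most was Sco2 (0 counts in ApccKO, 13.2±1.2 CPM in double knockout crypts, at least 97.8-fold higher at 3 counts per library, adjusted p = 8.9e-06, uncertain because of shared reads). Next were the glutamate receptor gene Gria3 (ENSMUSG00000001986, 0.222±0.15 to 15.8±1.2 CPM, 6.10±0.70, adjusted p = 3.5e-06) and the membrane protein gene Ano3 (ENSMUSG00000074968, 1.14±0.22 to 55±5.9 CPM, 5.59±0.68, adjusted p = 8.1e-06). The carboxylesterase gene Ces2f (ENSMUSG00000062826, 5.32±0.43, adjusted p = 5.2e-08) and Cpt1c (0.969±0.45 to 33.3±2.2 CPM, 5.09±0.44, adjusted p = 1.7e-07) followed. Lowered most were nitric oxide synthase 2, Nos2 (ENSMUSG00000020826, 20.2±21 to 1.14±0.57 CPM, -4.16±0.76, adjusted p = 0.00039), and chymosin, Cym (ENSMUSG00000046213, 12.6±2.7 to 0.83±0.64 CPM, -3.86±0.62, adjusted p = 0.00011). They were followed by Fstl4 (ENSMUSG00000036264, -3.35±0.42, adjusted p = 6.8e-06), H19 (29.5±9.3 to 3.01±0.47 CPM, -3.29±0.72, adjusted p = 0.0018) and gastrokine 3, Gkn3 (ENSMUSG00000030048, -3.06±0.39, adjusted p = 9.5e-06).

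The p53 list had 32 of 38 higher and 0 lower by edgeR without Apc on day 2 (0 lower at an unadjusted p under 0.05 and by DESeq2), by either adjustment (camera adjusted p = 1.9e-22). The call was lost at adjusted p = 0.11 with an estimated correlation. Dcxr (14.4±2.2 to 109±12 CPM, 2.92±0.15, adjusted p = 1.4e-10), Ccng1 (2.94±0.19, adjusted p = 3.4e-09) and Zmat3 (2.82±0.21, adjusted p = 2.2e-08) rose. Stem cell markers were lower in 18 and higher in 1 of 25 (19 and 2 adjusted over the list alone, camera adjusted p = 8e-09). Their call was lost at adjusted p = 0.25 with an estimated correlation. Lgr5 fell from 216±51 to 36.1±6.8 CPM (-2.58±0.26, adjusted p = 1.3e-06) and Olfm4 from 1980±110 to 376±100 CPM (-2.39±0.25, adjusted p = 1.5e-06). Smoc2 (-1.75±0.19, adjusted p = 1.9e-06) and Aqp4 (-2.20±0.24, adjusted p = 2.4e-06) fell as well. Wnt targets were lower in 11 and higher in 4 of 28 (13 and 5 adjusted over the list alone, camera adjusted p = 0.033, lower). This ended at adjusted p = 0.57 with an estimated correlation, and the median of the list (-0.23) and its mean (0.05) differed in sign. The ligand gene Wnt10a (ENSMUSG00000026167, 3.51±0.36, adjusted p = 1.2e-06) and cyclin D1, Ccnd1 (ENSMUSG00000070348, 182±7.2 to 682±77 CPM, 1.91±0.26, adjusted p = 2.1e-05), were higher. S phase genes were lower in 31 of 32, by either adjustment (camera adjusted p = 9e-21), with Uhrf1 at -1.38±0.17 (adjusted p = 3.8e-06). The call ended at adjusted p = 0.25 with an estimated correlation. G2 and M phase genes were lower in 31 of 34 (33 adjusted over the list alone, camera adjusted p = 4.7e-19), with Mki67 at -1.22±0.17 (adjusted p = 1.3e-05). It was lost at adjusted p = 0.32 with an estimated correlation. The Notch pathway had 5 higher and 7 lower of 20, by either adjustment (camera adjusted p = 0.62, median -0.12, mean 0.12, test lower). Notch3 (2.90±0.41, adjusted p = 3.5e-05) and Jag1 (1.55±0.20, adjusted p = 1e-05) rose, and Lfng fell (-1.36±0.17, adjusted p = 5.2e-06).

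Goblet markers were higher in 11 and lower in 3 of 22 without Apc on day 2 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0047). They were lost at adjusted p = 0.43 with an estimated correlation. Tff3 (162±22 to 422±44 CPM, 1.38±0.12, adjusted p = 9e-08) and the mucin gene Muc2 (ENSMUSG00000025515, 463±47 to 1130±52 CPM, 1.29±0.14, adjusted p = 1.1e-06) rose, as did Fcgbp (1.37±0.18, adjusted p = 7.4e-06). Enteroendocrine markers were higher in 15 and lower in 2 of 25, by either adjustment (camera adjusted p = 0.00016), with Gip (1.65±0.16, adjusted p = 3.3e-07) and somatostatin, Sst (ENSMUSG00000004366, 1.86±0.25, adjusted p = 1.4e-05), higher. Fetal genes were higher in 17 and lower in 1 of 25 (17 and 2 adjusted over the list alone, camera adjusted p = 0.00015). Both lists ended at adjusted p = 0.33 with an estimated correlation. The annexin gene Anxa8 (ENSMUSG00000021950) rose from 1.62±0.6 to 46.7±8.4 CPM (4.84±0.52, adjusted p = 2.1e-06). Tuft markers were higher in 7 and lower in 1 of 19, by either adjustment (camera adjusted p = 0.026), and enterocyte genes higher in 7 of 31 (5 adjusted over the list alone, camera adjusted p = 0.00082). Each was lost at adjusted p = 0.57 with an estimated correlation. Ribosomal proteins were higher in 42 of 79 (49 adjusted over the list alone, camera adjusted p = 3.5e-07) and immune markers in 14 of 29 (18 adjusted over the list alone, camera adjusted p = 0.00024). Here, too, the values were adjusted p = 0.57 with an estimated correlation. Alox5 (4.30±0.43, adjusted p = 5.7e-07), the brush border enzyme gene Alpi (ENSMUSG00000079440, 156±54 to 866±110 CPM, 2.47±0.56, adjusted p = 0.0023) and Cd7 (ENSMUSG00000025163) of lymphocytes (1.18±0.28, adjusted p = 0.003) rose. In the integrated stress response 6 were higher and 1 lower of 28, by either adjustment (camera adjusted p = 0.62), led by Ddit3 (1.16±0.15, adjusted p = 1.1e-05). Paneth markers had 0 of 19 called by edgeR (1 lower at an unadjusted p under 0.05, 0 by DESeq2, camera adjusted p = 0.84).

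**Figure D4:**
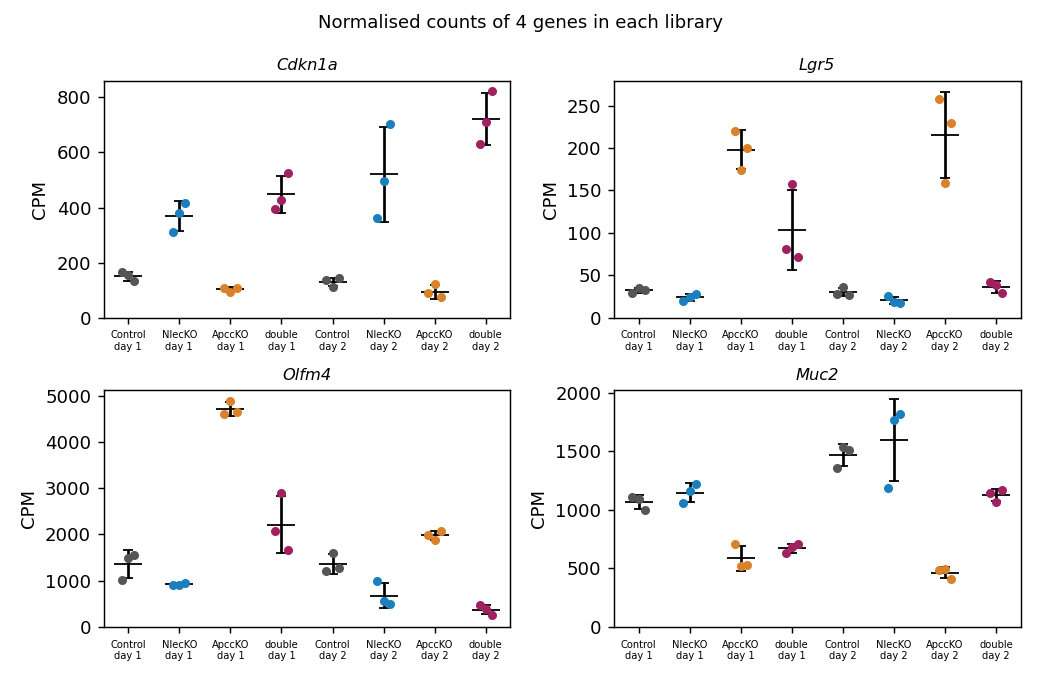
Cdkn1a, Lgr5, Olfm4 and Muc2 in CPM per library, with 3 mice per group and the mean ± SD drawn. On day 2, Lgr5 lies at 216±51 CPM in ApccKO and 36.1±6.8 CPM in double knockout crypts, and Muc2 at 463±47 and 1130±52 CPM.

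The interaction of the 2 losses tested whether the Nle1 effect differed with Apc state. On day 1 the interaction was called for 2 genes, with 1058 at an unadjusted p under 0.05 and 46 called by DESeq2. The imprinted RNA Meg3 (ENSMUSG00000021268, 2.70±0.44, adjusted p = 0.041) and the Max partner gene Mxd4 (ENSMUSG00000037235, 0.83±0.13, adjusted p = 0.041) rose on Nle1 loss without Apc and were not called with Apc intact (adjusted p = 0.81 for each). Their calls ended with another scaling (adjusted p = 0.051 for each), with the stricter filter (adjusted p = 0.057 for each) and when only the libraries compared were fitted (adjusted p = 0.063 and 0.093). The count was 0 to 7 with single libraries left out. No list had a gene called over all genes by edgeR. Adjusted over the list alone, 4 p53 targets and 1 fetal gene were higher and 1 fetal gene lower. At an unadjusted p under 0.05, 13 p53 targets and 17 ribosomal proteins were higher, and DESeq2 called 1 and 0 of these. Camera put p53 targets (adjusted p = 1.7e-08) and ribosomal proteins (adjusted p = 2.7e-14) higher. Each call was lost at adjusted p = 0.61 with an estimated correlation.

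On day 2 the Nle1 effect differed with Apc state. A change from day 1 was not tested. Some stem cell markers, Lgr5 among them, had a lower response when Apc was lost, and some goblet markers and p53 targets a higher one. The interaction was called for 868 genes, 545 higher and 323 lower, of which 361 differed at least 2-fold. The higher share of 62.8% was 37.4% with the stricter filter and 39.6% when only the libraries compared were fitted. Raised most were Sco2 (adjusted p = 0.0038, no size given because ApccKO crypts had 0 counts), Gsdmc2 (5.46±1.0, adjusted p = 0.005) and Alox5 (3.88±0.53, adjusted p = 0.00035). The first 2 are uncertain because of shared reads, and Gsdmc2 lay at only 0.197±0.076 CPM in ApccKO crypts. Lowered most were H19 (-5.48±1.3, adjusted p = 0.023), Cym (-4.84±0.81, adjusted p = 0.0028) and Nos2 (-3.57±1.0, adjusted p = 0.045). Stem cell markers had 9 of 25 lower (14 adjusted over the list alone, camera adjusted p = 2e-13). It then fell away, at adjusted p = 0.23 with an estimated correlation. Lgr5 (-2.01±0.36, adjusted p = 0.0043), the ion transporter gene Slc12a2 (ENSMUSG00000024597, -0.83±0.16, adjusted p = 0.0051) and Cdca7 (ENSMUSG00000055612, -0.78±0.17, adjusted p = 0.011) were lower. Goblet markers had 7 of 22 higher (9 adjusted over the list alone, camera adjusted p = 0.00026). Their call ended at adjusted p = 0.33 with an estimated correlation. Tff3 (1.19±0.16, adjusted p = 0.00033), Muc2 (1.17±0.19, adjusted p = 0.0016) and Fcgbp (1.49±0.25, adjusted p = 0.0017) were higher. Wnt targets had 4 of 28 lower (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00011), and S phase genes 2 of 32 (22 adjusted over the list alone, camera adjusted p = 5.4e-15). Both ended at adjusted p = 0.33 with an estimated correlation.

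In the day 2 interaction the p53 list had 8 of 38 higher (13 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00043). The list no longer passed, at adjusted p = 0.66 with an estimated correlation. Dcxr (1.44±0.19, adjusted p = 0.00032), Ei24 (0.57±0.11, adjusted p = 0.0043) and the peptide transporter gene Tap1 (ENSMUSG00000037321, 1.74±0.32, adjusted p = 0.0043) were higher. Ribosome biogenesis (0 and 4 at an unadjusted p under 0.05, 1 lower by DESeq2) and G2 and M phase genes (0 and 1, 0 by DESeq2) had 0 called by edgeR. Camera put each list lower (adjusted p = 0.00027 and 0.00011), lost at adjusted p = 0.83 with an estimated correlation. Krt19 (0.94±0.19, adjusted p = 0.0071) of the fetal list was higher and Amotl2 (ENSMUSG00000032531) of the Hippo pathway lower (-1.02±0.21, adjusted p = 0.008). The count of 868 was 452 and 499 without ApccKO replicates 1 and 3, 564 and 374 without double knockout replicates 2 and 3, and 527 and 492 without Control replicates 1 and 3. H19 lost its call without double knockout replicate 3, Control replicate 1 or NlecKO replicate 3 (adjusted p = 0.056 to 0.075). Nos2 lost it without any of 8 single libraries, all but Control replicate 2, NlecKO replicate 1 and ApccKO replicates 1 and 3 (adjusted p = 0.059 to 0.13).

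Across genes, which are not independent replicates, the effects of Nle1 loss with and without Apc correlated at 0.286 (Pearson) and 0.459 (Spearman) on day 1 and at 0.47 and 0.517 on day 2, in comparisons that share no library. The Pearson values depended on the filter and method: they were 0.0637 and 0.175 with no filter, 0.496 and 0.579 with the stricter filter, and 0.0972 and 0.216 by DESeq2. On day 1, 296 genes were called in both, 106 higher and 190 lower in each and 0 in opposite directions, where independent lists would share 8.46 and 12.7. On day 2, 1750 were called in both, of which 1706 had the same sign (805 higher and 901 lower, 236 and 211 for independent lists) and 44 the opposite sign. Among the 868 genes of the day 2 interaction, 356 changed the same way and more without Apc, 24 the same way and less, and 488 had fitted changes of opposite sign, which selection by the interaction favours. Of these 868 genes, 626 were called for Nle1 loss only without Apc, 99 only with Apc intact, and 135 in both.

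**Figure D5:**
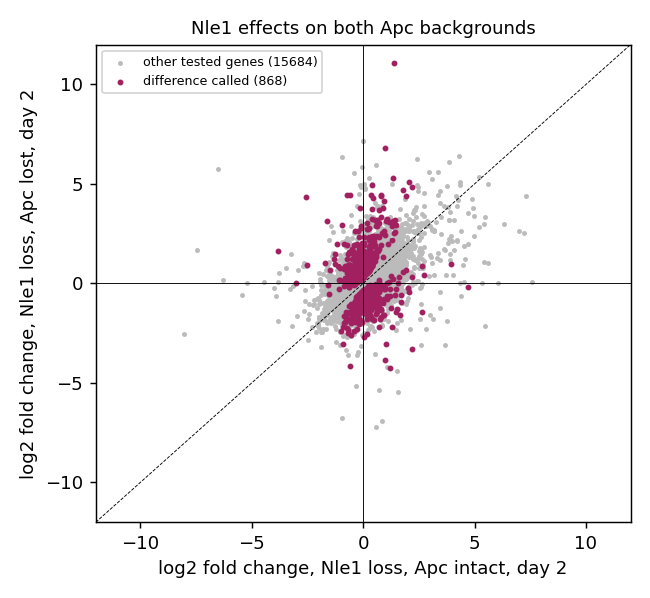
Log2 fold change by Nle1 loss on day 2 with Apc intact (horizontal) and with Apc lost (vertical), with 1 point per tested gene and the line of equal effects dashed. The 868 genes called in the interaction are coloured and the other genes are grey.

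Apc loss in crypts that lack Nle1, the double knockout against NlecKO, called 8708 genes on day 1 (4674 higher and 4034 lower) and 7920 on day 2 (4240 higher and 3680 lower). Wnt targets were higher in 22 and 24 of 28 on the 2 days and stem cell markers higher in 21 and 18 of 25, with 3 lower on day 2. Of 38 p53 targets, 25 and 29 were higher and 2 and 1 lower, on day 2 Sesn1 (ENSMUSG00000038332, -1.92±0.32, adjusted p = 0.00012). The G2 and M phase list had 27 of 34 higher on day 1 and 0 on day 2 by edgeR (0 at an unadjusted p under 0.05 and 0 by DESeq2). The days differed for 187 genes in the effect of Apc loss, 72 for Nle1 loss without Apc, 27 between the Control groups, and 1 for Nle1 loss with Apc intact. At an unadjusted p under 0.05 there were 2174, 2119, 1686 and 2151 genes, and DESeq2 called 485, 310, 144 and 218. With single libraries left out the counts were 66 to 403, 8 to 134, 0 to 82 and 0 to 190. The 1 gene was that of the receptor ErbB2, Erbb2 (ENSMUSG00000062312, -0.74±0.11, adjusted p = 0.041). Between the Control groups Klhl32 (ENSMUSG00000040387, 17.7±1.4 to 1.25±0.18 CPM, -3.80±0.63, adjusted p = 0.021), the p53 target Eda2r (11.3±3.8 to 3.14±1.2 CPM, -1.83±0.31, adjusted p = 0.022) and the axon guidance gene Slit2 (ENSMUSG00000031558, -1.22±0.20, adjusted p = 0.021) were lower on day 2 and the transcription factor gene Osr2 (ENSMUSG00000022330) higher (1.97±0.33, adjusted p = 0.021). Each call ended without any 1 of Control replicates 2 and 3 of either day (adjusted p = 0.09 to 0.16). Gsdmc3 (2.27±0.67 to 16.2±10 CPM, 2.83±0.51, adjusted p = 0.025) and H2-DMb1 (ENSMUSG00000079547) of antigen presentation (3.9±1.4 to 25.1±2.3 CPM, 2.68±0.51, adjusted p = 0.039, uncertain because of shared reads) were higher too. Their calls ended without any 1 Control library but replicate 1 of day 2 (adjusted p = 0.052 to 0.23). Of these 6 calls, 4 ended in the fit to only the libraries compared (adjusted p = 0.13 to 0.58), and those of Eda2r and H2-DMb1 ended with no filter (adjusted p = 0.052 and 0.087). Day after induction and day of collection were the same variable in this design.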

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

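Each result in this part was flagged because a test of the difference between 2 groups' effects passed: the interaction of Nle1 loss with Apc loss, or the difference of an effect between the days. The regroupings of the libraries and the test of immune markers without antigen presentation genes were planned before their results were seen, and every other test below was chosen after its result was seen.

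The interaction on day 1 was called for 2 genes, Meg3 (2.70, adjusted p = 0.041) and Mxd4 (0.83, adjusted p = 0.041); of 100 regroupings of these libraries, fitted to them alone, 6 called as many as the 1 gene of the real grouping, up to 47. Their calls ended in 14 and 13 of 20 other settings (adjusted p up to 0.35). The interaction on day 2 was called for 868 genes, with Sco2 (fitted at 9.71, adjusted p = 0.0038), Gsdmc2 (5.46, adjusted p = 0.005) and Alox5 (3.88, adjusted p = 0.00035) raised most and H19 (-5.48, adjusted p = 0.023), Cym (-4.84, adjusted p = 0.0028) and Nos2 (-3.57, adjusted p = 0.045) lowered most; of 19 settings, 10 ended the call of Nos2 (adjusted p up to 0.15) and 4 that of H19 (up to 0.075). The effect of Nle1 loss with Apc intact differed between days for 1 gene, Erbb2 (-0.74, adjusted p = 0.041), where the fit to these libraries alone called 0, so that all 100 of 100 regroupings called as many, up to 7; its call ended in 12 of 19 settings (adjusted p up to 0.38). The effect of Apc loss differed between days for 187 genes, with Vill (3.54, adjusted p = 0.0093), Pdlim7 (2.75, adjusted p = 0.0057) and Ltbp4 (2.11, adjusted p = 0.0057) raised and Sco2 (fitted at -8.96, adjusted p = 0.022), Ighg2b (-6.53, adjusted p = 0.042) and Car4 (-4.21, adjusted p = 0.0098) lowered; only the real grouping, 1 of 100, called its 108 genes, against at most 1 in the others. Without the 3 libraries that stood apart 1 ApccKO library is left on day 1, so no count is given. Of 20 settings, the fit without those 3 libraries among them, 14 ended the call of Ighg2b, 8 that of Sco2, 2 that of Car4, and 1 each those of Vill, Pdlim7 and Ltbp4. The effect of Nle1 loss without Apc differed between days for 72 genes, with Sco2 (fitted at 9.66, adjusted p = 0.021), Krt15 (3.59, adjusted p = 6.4e-05) and Cyp2e1 (1.87, adjusted p = 0.037) raised and Cym (-4.20, adjusted p = 0.024), Fstl4 (-2.75, adjusted p = 0.04) and Cap2 (-2.52, adjusted p = 0.013) lowered; 7 of 100 regroupings called at least the 96 genes of the real grouping, up to 4628, which points to a structure of the samples that the effects of the groups themselves can give. Of 20 settings, the fit without the 3 libraries that stood apart again among them, 12 ended the call of Cyp2e1, 11 that of Fstl4, 9 that of Cym, 6 that of Sco2, 2 that of Cap2 and 0 that of Krt15. The 3 fitted values of Sco2 rest on 0 counts in ApccKO crypts of day 2 and are not measured sizes.

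For comparisons of 3 with 3 libraries the 10 possible splits are too few for a share under 0.05. The real split called the most in 8 of 9 comparisons, 1 of 10 splits in each: Nle1 loss with Apc intact 6 against at most 1 on day 1 and 279 against 6 on day 2, Apc loss 7362 against 0 and 8726 against 1, Nle1 loss without Apc 535 against 8 and 6769 against 1, and Apc loss without Nle1 6915 against 1 and 7376 against 5. Between the Control groups of the 2 days, 2 of 10 splits called at least the 5 genes of the real split, and the other one called 1127, which points to a structure of these samples that is not the day.

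For the differences of the Nle1 effect with Apc state on day 2, 4 of 100 regroupings, the real one included, called as many as the real 871 genes, up to 4200. The regroupings mix both Apc states, so Apc loss enters their counts and spread. The share of 4 in 100 thus does not decide whether these differences came by chance. More complete loss of Nle1 without Apc was argued against, since the interaction on the Nle1 transcript was -0.06 with an SE of 0.23. A common factor scaling all effects was argued against as the whole cause: over all tested genes and factors from 0 to 4, at least 358 genes departed from it (112 to 430 at the fewest with single libraries left out), though fewer than the 868 at a factor of 1, so a factor near 1.7 stays open for a part. Whether more cells that escaped recombination stood in double knockout crypts on day 2 stayed open, because the Nle1 effect without Apc changed between days by 0.12 with an SE of 0.23. A biological difference in how crypts without Apc answer to Notchless loss remains a possible explanation, though any property that goes with the Apc cross or its run of codes could act in the same way.

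Rps3a lay at 7.02±1.7 CPM in the 12 libraries with Apc intact and at 564±47 CPM in the 12 with Apc lost, and Rplp0 at 73.8±13 and 1870±450 CPM, with no overlap. Gm5506 went the other way, at 142±29 CPM with Apc intact and 0.175±0.12 CPM with Apc lost, again with no overlap. Its sum with the copies Eno1 and Gm13699 was 753±130 and 669±120 CPM, so reads shared between copies fit Gm5506. For Rps3a, reads shared between near-identical copies fit the values, since the summed CPM of 4 copies differed by only 0.51 on the log2 scale (686 to 978 CPM). For Rplp0 the sum with its copy Gm8730 alone still differed by 3.57 (162 to 1930 CPM), so reads on copies not summed stayed open. Separate preparation or processing of the Apc cross could not be excluded as a cause for Rplp0. Gm8730 differed 120-fold among the 3 ApccKO libraries of day 1, but a batch of the Apc-lost codes is confounded with Apc loss. A strain variant against the reference was not tested, and a biological rise by Apc loss was not tested apart from these.

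Immune cell markers fell on Apc loss, by a median of -2.47 on day 2. Equal dilution of other cells by epithelium was argued against only as the whole cause. Stromal and endothelial markers fell less (median -0.83), a difference of -1.64 (permutation p = 0.00021 over 100000 permutations, which treat genes as independent). Their sum was low, 64.3±30.4 CPM in Control of day 2. A fall of antigen presentation genes of the epithelium alone was argued against, since the 26 markers left without H2-Aa, H2-Ab1 and Cd74 had a median of -2.61. Fewer immune cells among the crypts and a loss of them in preparing the crypts could not be told apart here, because no cells were counted.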

How the results depend on the processing

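Counts of genes for Apc loss stayed within 1.5 times their value in every alternative on each day, and among calls of named genes, as kept and lost, DESeq2 gave 429 and 0, DESeq2 size factors 423 and 6, the stricter filter 422 and 3, a term for sex (chosen after seeing the data) 427 and 2, no filter 396 and 33, and the fit to only the libraries compared 324 and 102. The counts that moved were the following, with the value of the alternative in each case; except for fits to fewer libraries, which have less to estimate the spread from, the cause was not tested. With no filter the counts were 266 for Nle1 loss with Apc intact on day 1 (411), 0 for its difference between days (1), 118 for that of Apc loss (187) and 17 between Control groups (27). By DESeq2 they were 802 for Nle1 loss with Apc intact on day 1, 46 for the interaction of day 1 (2), and 218, 485, 310 and 144 for the differences between days of Nle1 loss, Apc loss, Nle1 loss without Apc (72) and Control. Fitted to only the libraries compared they were 6 and 279 for Nle1 loss with Apc intact on days 1 and 2 (2581), 535 for Nle1 loss without Apc on day 1 (1762), 1 for the interaction of day 1, and 0, 108 and 5 for the differences between days of Nle1 loss, Apc loss and Control. DESeq2 size factors gave 0 for the interaction of day 1 and 0 for the day difference of Nle1 loss, and the stricter filter 0 and 4. A term for sex gave 4 for the interaction of day 1 and 211, 113 and 50 for the day differences of Nle1 loss, Nle1 loss without Apc and Control. Replicate numbers did not pair libraries (0 of 14 comparisons), and with a replicate block the counts were 0 for the interaction of day 1, 2 for the day difference of Nle1 loss and 16 for Control, with 417 calls of named genes kept and 12 lost.

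Leaving out the 3 libraries that stood apart, chosen after seeing the data, kept 1 ApccKO library on day 1. Such a fit cannot tell lost replication from dependence on them, so its counts are not given. The correlation of Nle1 effects on day 1 (0.286) was 0.0637 with no filter, 0.496 with the stricter filter, 0.0972 by DESeq2 and 0.372 with the libraries of that day only, and that of day 2 (0.47) was 0.175, 0.579 and 0.216 under the first 3 of these. Of 71 list calls by camera among 108, 3 held with an estimated correlation. Ribosome biogenesis genes turned from lower to higher for Nle1 loss with Apc intact on day 1 without NlecKO replicate 1 (adjusted p = 0.039), and with single libraries left out this p ranged from 2.4e-05 to 0.91.

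With single libraries left out, in order of the days, counts were 29 to 1159 and 1206 to 2818 for Nle1 loss with Apc intact, 6645 to 8022 and 8564 to 9679 for Apc loss, 600 to 2147 and 4277 to 5040 for Nle1 loss without Apc, 7061 to 8720 and 6590 to 7839 for Apc loss without Nle1, and 0 to 7 and 374 to 1222 for the interaction. Differences between days ranged over 0 to 190 for Nle1 loss (190 without Control replicate 1 of day 1, 181 without NlecKO replicate 1 of day 2), 66 to 403 for Apc loss (403 without Control replicate 2 and 66 without Control replicate 3 of day 2), 8 to 134 for Nle1 loss without Apc (134 without double knockout replicate 3 of day 1, 8 without ApccKO replicate 3 of day 2) and 0 to 82 for Control (82 without replicate 1 and 0 without replicate 3 of day 1). The correlations were 0.198 to 0.296 on day 1 and 0.378 to 0.449 on day 2, and 68 to 75 list calls passed.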

Other observations

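Of day 2 interaction genes also called for Apc loss on day 1, 629 (96%) had an interaction opposite in sign to the Apc effect. Selection favours this, as the interaction subtracts the Apc effect of day 2, which mostly had the sign of day 1. Tff3, Muc2 and Alox5 belonged to the genes lowered by Apc loss and raised by the added loss of Nle1, and Lgr5 to those raised and then lowered. Over all genes, the effects of Apc loss on day 1 and of Nle1 loss without Apc on day 2, which share no library, correlated at -0.293 (Pearson) and -0.374 (Spearman); genes are not independent replicates. The mirror pair, Apc loss on day 2 and Nle1 loss without Apc on day 1, correlated at -0.0716 and -0.222. With Apc intact the same pairs gave 0.0923 and -0.0092, and -0.0685 and -0.259.

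Among Control libraries Lct lay at 1180, 459 and 339 CPM in replicates 1 to 3 of day 1 and 1040, 258 and 1080 CPM in those of day 2. The Control split that called 1127 genes set the 3 with the most Lct apart. Lct was chosen after its values were seen.

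Double knockout replicate 2 of day 1 had Y-linked genes at a mean of 0.233 CPM, as in female libraries, and Xist at 2.62 CPM, as in male libraries; the other female libraries had Xist at 847 to 1770 CPM. These genes were chosen after their values were seen.

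Genes next to Apc could differ if variants were carried with its allele. Set after seeing the data, this was tested on the 50 tested genes on either side. Of these 100, 7 separated all Apc-lost from all Apc-intact libraries 2-fold or more, against 1330 of 15562 other genes (8.55%, Fisher exact p = 0.72). No excess was found, and genes near Nle1 were not tested.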
